A study of Colossoma macropomum with 10 samples.

How the data were processed

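RNA sequencing libraries from the trunks of 10 juvenile tambaqui (*Colossoma macropomum*), each fish with its head removed and giving 1 library, were analysed from the tables the authors deposited. Per the labels' protocols, 20 juveniles were chosen by size, the 10 RNA samples of best quality were kept, and libraries were made with a strand-specific mRNA kit. Per the submitters' processing notes, the reads passed through bcl2fastq 2.17, FastQC, Trimmomatic and RSEM. The versions of the last 3 tools, the aligner and the assembly settings are not given in the sources used here.

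Each deposited table held 742682 assembled transcripts in 648736 Trinity genes, with a median transcript length of 335 bp. Per the file headers, the authors gave each transcript an expected count, which is RSEM's estimate of the reads or fragments it produced and need not be whole. The deposited TPM and FPKM values were scaled by the authors for effective transcript length and library total, and the deposited isoform percentage (percent) is a transcript's part of its gene's TPM. Transcripts carried assembly identifiers only. None matched the gene table of the *Colossoma macropomum* reference annotation supplied beside the data, so that table was not used. The lists of gonad, tissue and pathway genes fixed before the data were examined could therefore not be tested.

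Assembled fragments of a gene, alleles and near-identical copies can appear as separate Trinity genes, and RSEM divides reads that match several of them by estimation. Counts of "genes" below are counts of Trinity genes, which outnumber the genes of a fish, and reads shared between copies make the level of any 1 of them uncertain.

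Expected counts were summed per Trinity gene and rounded to whole numbers. Totals ranged from 22714719 to 43469240 expected counts per library. CPM was computed as the count scaled to the library total. A count of 0 allows a level of up to 3 counts, which was 0.069 to 0.132 CPM depending on the library. Shares of counts carry 95% Wilson intervals. For the shares of 0.1% or more given for single libraries, the interval reached at most 0.02 percentage points to either side. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

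The labels put all fish in 1 group and give no sex. Body size is the only label besides the fish number that differed, so the design followed size. Size rose nearly in step with the fish number. A trend over size therefore cannot be told from a trend over that number or an order that followed it. The 10 libraries are separate fish. Choices of test, filter, covariate, alternative and rule for naming features were made before the data were examined, except where stated. Trends over size were fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest) on genes kept by filterByExpr with its minimum count of 10, with TMM scaling and size in cm as a number. The Benjamini-Hochberg threshold was 0.05. The same fit was run per transcript, and edgeR's diffSpliceDGE tested whether the mix of transcripts of a gene changed with size. Standard errors of slopes were derived from the quasi-likelihood F statistic. The features named are the 2 with the smallest p that rose and the 2 that fell.

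Distances between libraries were root-mean-square log2 differences over the 500 most different genes, and Spearman rho was computed on log2 CPM with a prior count of 2. Distance was set against difference in size with a one-sided Mantel permutation test. The number of genes at 1 CPM or more was set against size with two-sided permutation tests. Each test used 100000 permutations with 10 libraries and all 5040 or 362880 permutations with 7 or 9. A gene was called on-off when it had at least 1 CPM in some libraries and 0 counts in all others, and patterns were compared with 100 independent shuffles of each gene's libraries.

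Alternatives covered DESeq2 1.42.0, limma 3.58.1 (voom, and limma trend on log2 of TPM or FPKM with a pseudocount of 1), other scaling, filters and forms of size, each library left out, and 1 surrogate variable from sva 3.50.0. After the data were examined, fits without J11, J12 and J13 and a fit without the 15 most abundant genes were added. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

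The size fit was tested on simulated counts for the 55857 genes it ran on. It called 0 of 100 genes given a log2 slope of 1 per cm and 47 of 100 given a slope of 3, with 2 false calls. Of the unchanged simulated genes, 4.36% had an unadjusted p under 0.05. The simulation changed 200 genes in all, drew genes independently and set no libraries apart from the rest. Its rates therefore need not hold for the real fit, which also called genes with slopes of less than 1 per cm. The test of isoform use, simulated over 12106 genes, found 1 of 100 genes at a slope of 2 and 21 of 100 at a slope of 4. It made 17 false calls, so its error rate was not held at the threshold.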

Results

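The series concerns the tambaqui, a South American freshwater fish, around the onset of gonad differentiation. RNA was measured in the trunks of 10 juveniles taken before sex can be seen in histological sections. The fish carry the numbers J1, J2, J3, J4, J6, J8, J9, J11, J12 and J13. In that order they measured 1.7, 2.1, 2.3, 2.2, 2.6, 2.6, 3.1, 3.1, 3.3 and 3.3 cm. J1 lay below the range of 21 to 33 mm stated for the collection. Depth ran from 22714719 expected counts in J8 to 43469240 in J2. The labels name no sex and no treatment, so the fish form 1 group, and no comparison between the sexes was made. The question that the labels allow is whether transcript levels followed body size.

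The transcriptomes of J11, J12 and J13 were alike and lay apart from the other 7. Spearman's rho of log2 CPM was 0.929 to 0.941 among these 3 libraries and 0.615 to 0.687 between them and the other 7. Among the other 7 it was 0.807 to 0.910. Equal size did not bring J9 and J11 together: both fish measured 3.1 cm, and their rho was 0.666. The pair at 2.6 cm, J6 and J8, had a rho of 0.808, and the pair at 3.3 cm, J12 and J13, a rho of 0.935. The first principal component held 56.0% of the variance, with scores of 301.0 to 309.5 in J11, J12 and J13 and of -162.2 to -87.1 in the others. The labels name no batch, dissection or library date that marks these 3 fish.

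**Figure D1:**
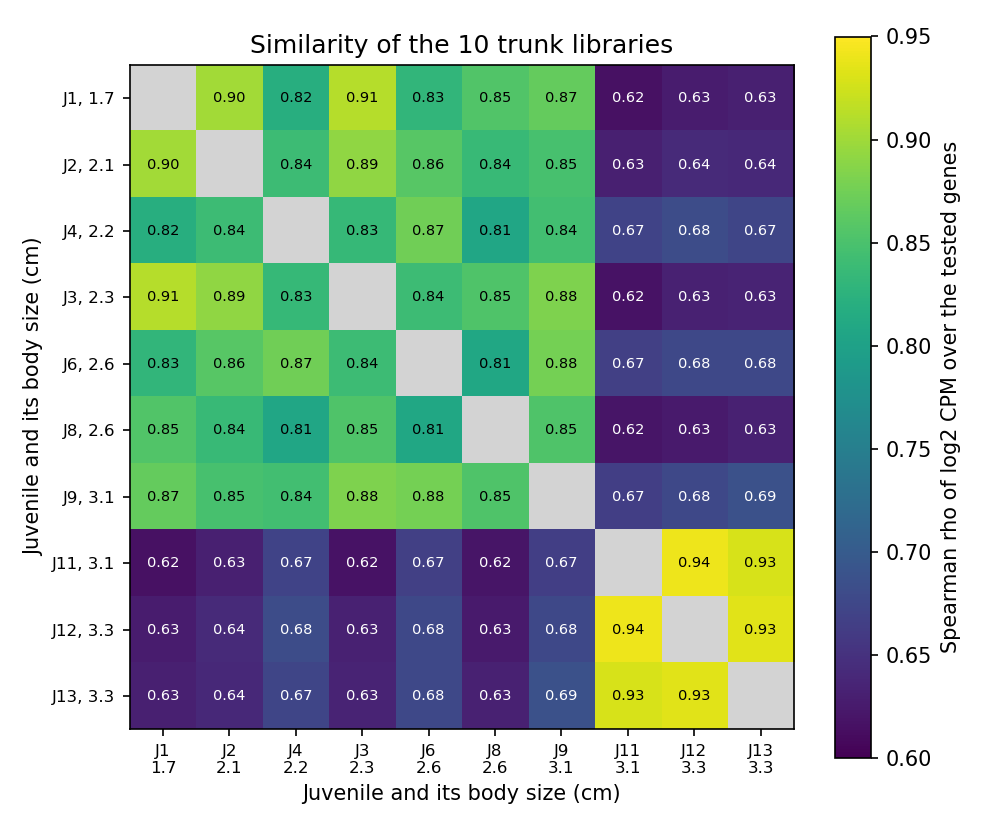
Spearman's rho of log2 CPM over the tested genes for each pair of the 10 trunk libraries, with fish ordered by body size in cm on both axes and the diagonal left grey. J11, J12 and J13 share values of 0.929 to 0.941, and their values with the other 7 libraries are 0.615 to 0.687.

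The gene with the highest mean abundance was TRINITY_DN202972_c27_g1, singled out after its values were seen. It held 7.07% (J9) to 13.4% (J1) of all counts in J1 to J9. In J11 it held 0.0011% (95% Wilson interval 0.000996 to 0.00122%), or 376 counts. In J12 it held 0.00122% (0.00112 to 0.00132%), and in J13 0.000962% (0.000867 to 0.00107%). The 15 genes of highest mean abundance together held 22.4% of the counts in J9 and 51.8% in J3, the lowest and highest of the 7 libraries. They held 6.19% in J11, 6.99% in J12 and 7.02% in J13. Of the 100 most abundant genes, 31 in J11, 31 in J12 and 27 in J13 lay under 1% of their highest level. The other libraries had 0 to 7 such genes. Counts were also summed over all genes that share the DN number of their Trinity identifier, a wider grouping than a Trinity component. Of the 100 most abundant such groups, 19, 19 and 18 did so in these 3 libraries, and 0 to 3 in the others. Such a group can join genes of unlike pattern: 1 held a gene at 3.0 CPM in J11 and 9842.7 in J1, and another at 554.0 and 6795.4. The lower counts of groups therefore need not reflect the joining of copies alone. Each of the 31, 31 and 27 genes still had counts in J11, J12 and J13, with at least 10 in each library. The most abundant genes and groups were ranked by mean CPM over all 10 libraries. Such a ranking favours genes high in the other 7 libraries over genes high only in J11, J12 and J13. Part of these contrasts was therefore set by the ranking.

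A second abundant gene, TRINITY_DN117040_c3_g1, also singled out after its values were seen, separated the smaller from the larger fish. It held 2.24, 15.3, 19.4 and 5.78% of the counts in J1, J2, J3 and J4, the 4 fish of up to 2.3 cm. In the 6 fish of 2.6 cm or more it held 0.142 to 0.297%. Mean log2 CPM was 16.26 ± 1.42 (SD, n = 4) in the smaller and 10.99 ± 0.36 (SD, n = 6) in the larger fish, a difference of 5.28. No test is given, since the gene was picked by these values. Among the 4 smaller fish the smallest, J1, had the lowest share and the longest, J3, the highest, opposite in direction to the difference between the classes. This order within 4 fish was not tested.

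**Figure D2:**
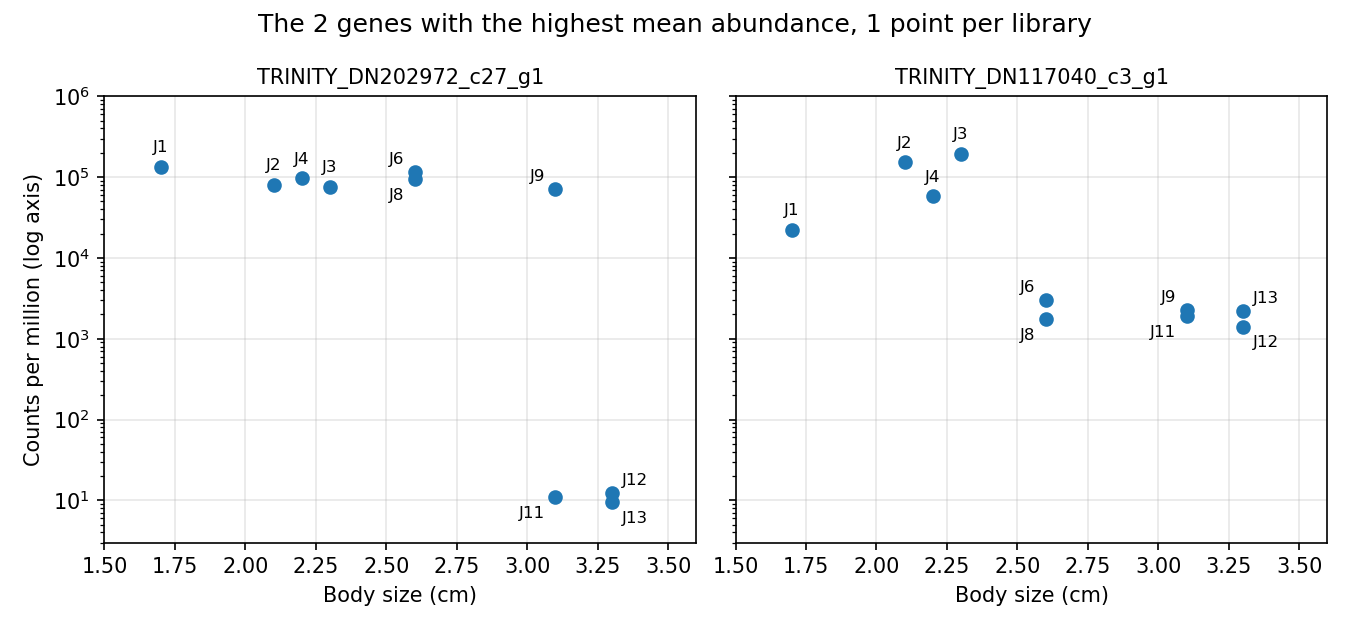
Level in CPM, counts scaled to the library total (log axis), against body size in cm for the 2 genes with the highest mean abundance, with 1 point per library and no error bars. TRINITY_DN202972_c27_g1 is at 70662 CPM in J9 and at 9.6 to 12.2 CPM in J11, J12 and J13, and TRINITY_DN117040_c3_g1 is high in the 4 fish of up to 2.3 cm.

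Over all 10 fish, 5149 of 55857 tested genes followed body size past the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg). Of these, 3773 rose and 1376 fell as size increased, a balance that shifted to 4369 and 4166 with limma-voom and to 6213 and 615 with total count alone. Total count alone leaves out the TMM factors, which were 0.615 to 1.03 in J1 to J4 and 1.24 to 1.33 in J11, J12 and J13. Leaving them out favours rising genes. Without J11, J12 and J13, which are 3 of the 4 largest fish, the same edgeR test over the other 7 called 0 of 50593 genes. There, 2845 genes had an unadjusted p under 0.05, where chance gives 2530, and the smallest adjusted p was 0.871. Single libraries also decided the count. It was 2 without J2, 3 without J12, 4 without J13 and 397 without J11. It was 1347 without J1, 1661 without J3 and 11481 without J9. With all 10 fish, 16605 genes had an unadjusted p under 0.05 in the edgeR test. That number was 15497 of 63717 without J2, 10343 of 52119 without J12 and 10432 of 52243 without J13. In these 3 fits few genes passed the adjusted threshold, but far more than the 5% that chance gives kept a small unadjusted p. The number of calls therefore depended on J11, J12 and J13 and on single other fish. Of the 1376 genes that fell, 1365 passed the count filter in the other 7 fish, and each of these had a negative slope, 538 of them with an unadjusted p under 0.05. The median slope of these 1365 genes was -1.75 log2 units per cm over 10 fish and -1.19 over the 7. Of the 3773 that rose, only 2544 passed that filter, which removes genes with few counts outside J11, J12 and J13, and 2468 had a positive slope, 488 of them with an unadjusted p under 0.05. The median slope of these 2544 genes was 1.64 over 10 fish and 0.73 over the 7. These 7 libraries were part of the first fit, and the genes were chosen by their slopes in it, so the values over 7 fish are no evidence of a trend of their own.

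**Figure D3:**
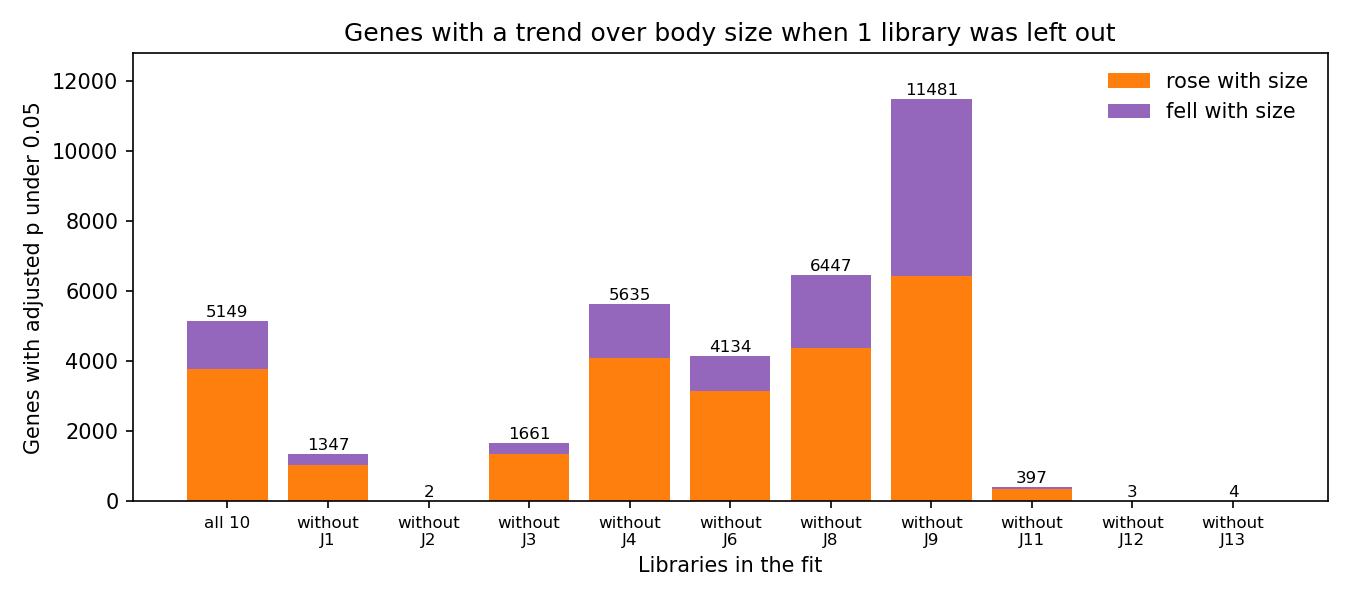
Number of genes past the threshold of the size trend with all 10 libraries and with each library left out, split into genes that rose (orange) and fell (purple) with size. The count is 5149 with all 10 and falls to 2, 3 and 4 without J2, J12 and J13.

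Among features named by the rule, TRINITY_DN200388_c2_g4 rose by 3.55 ± 0.32 (SE, n = 10) log2 units per cm, with an edgeR adjusted p of 0.00827. Its TMM-scaled level was 0.196 CPM in J1, 1.21 in J6, 2.49 in J9 and 7.34, 12.1 and 9.6 in J11, J12 and J13. In the other 7 fish its slope was 2.54 ± 0.47 (SE), with an edgeR adjusted p of 0.871. TRINITY_DN199115_c9_g6 had 0 counts in all 6 fish of up to 2.6 cm and 47, 110, 166 and 169 counts in J9, J11, J12 and J13. Its edgeR adjusted p was 0.00827, and its fitted slope depends on the prior count and is not given. It did not pass the count filter in the fit without J11, J12 and J13. A count of 0 allows a level of up to 3 counts in each of those 6 libraries.

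TRINITY_DN197246_c1_g4 had a slope of -2.75 ± 0.35 (SE, n = 10) log2 units per cm, with an edgeR adjusted p of 0.0171. It went from 2.31 TMM-scaled CPM in J1 to 0.264 in J9 and 0.111 in J13. TRINITY_DN163868_c0_g1 had a slope of -2.23 ± 0.31 (SE, n = 10), with an edgeR adjusted p of 0.0171, and went from 2.58 CPM in J1 to 0.264 in J9 and 0.199 in J13. In the other 7 fish the slopes of these 2 genes were -2.62 ± 0.59 and -2.56 ± 0.50 (SE), close to those over all 10, with an edgeR adjusted p of 0.871 for each. The 2 genes were picked by a fit that included these 7 fish, so the closeness is no evidence of its own. Both genes were at low depth, with 5 to 67 counts per library.

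At the level of single transcripts, 2564 of 76944 followed size past the threshold in the edgeR test, 2237 of them rising and 327 falling, a balance that shifted to 7221 and 5139 with DESeq2. Without J11, J12 and J13 the count was 0 of 70218, with 2811 transcripts at an unadjusted p under 0.05, fewer than the 5% that chance gives. The mix of transcripts within a gene changed with size for 429 of 12106 genes (edgeR diffSpliceDGE, gene-level F test). Without J11, J12 and J13 it did so for 1 of 11242. The isoform test did not hold its error rate in simulation, so the 429 genes include an unknown number of false calls.

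Among the 7 fish J1 to J9, no positive relation between likeness in size and likeness of the transcriptomes was detected. The one-sided test used could not detect a negative relation. The Mantel correlation between distance and difference in size was -0.338 (exact one-sided permutation p = 0.905, n = 7). Over all 10 libraries, the test planned beforehand gave a positive relation with a one-sided permutation p = 0.023, or 0.069 adjusted over 3 relations. The libraries fall into separate clusters, so no pooled coefficient is given here, and J11, J12 and J13 are too few for a value of their own. The number of genes at 1 CPM or more ranged from 21759 in J3 to 29383 in J9. Among the 7 fish its relation to size had a Pearson r of 0.315 (exact permutation p = 0.495) and a Spearman rho of 0.414 (exact permutation p = 0.357). Without the 2 fish farthest from the median size, r was 0.317. Benjamini-Hochberg adjustment over these 3 relations gave permutation p = 0.905, 0.742 and 0.742 in the order given (exact tests).

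In all, 940 genes had at least 1 CPM in some libraries and 0 counts in every other. The most frequent pattern was presence in J6 alone, with 187 genes, where shuffling gave 30.07 on average and at most 44. Another 103 genes were present in J1 to J9 and absent from J11, J12 and J13, where shuffling gave 1.08 on average and at most 5. A further 68 were present in J11, J12 and J13 alone, where shuffling gave at most 4. Other patterns cut across that division. The pattern of J2, J4 and J6 held 20 genes, where shuffling gave at most 5. The pattern of J4, J6, J11, J12 and J13 held 16 genes, where shuffling gave at most 2.

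The spread between fish after the size trend, edgeR's biological coefficient of variation, was 0.675. It was 0.581 over the 7 fish without J11, J12 and J13.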

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

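The measures and the ratio that singled out libraries here were set up after the data were examined. Of 17 measures compared over the 10 libraries, 4 had a library set far from the rest. Chance would give about 0.85 if every measure were normally distributed, which was not checked. Some of the measures depend on each other, such as the gene counts of J8 before and after thinning. The ratio compares the most extreme library with the next, so it passes over libraries that lie together, such as J11, J12 and J13.

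J8 had 117326 genes with at least 1 expected count, below the 173453 to 206686 of the other 9 libraries. J8 was also the shallowest library. With every library thinned to its depth, J8 still had the fewest, 117326 against 147466 to 172537 in the others.

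J6 alone held 187 genes at 1 CPM or more with 0 counts in every other library, against 3 to 28 such genes in each of the others. They held 0.0786% of the counts of J6, with a highest level of 128.0 CPM.

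The fragment length implied by the effective lengths in the tables was 293.6 bp in J13, above the 243.8 to 269.0 bp of the others.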

How the results depend on the processing

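Fits without J11, J12 and J13 and without the 15 most abundant genes were chosen after the data were examined; the other alternatives were not. The 5149 size genes (3773 rising, 1376 falling) became 11960 with DESeq2 (6809 and 5151), 8535 with limma-voom (4369 and 4166), 11061 on log2 TPM (9628 and 1433) and 10322 on log2 FPKM. The count was 17953 with no filter (9917 and 8036) and 2223 at 5 CPM in 5 libraries, where fewer genes were tested. It was 2953 on log2 size, and 23 with 2 size classes (3 and 20). It was 0 in edgeR with 1 surrogate variable, with 9392 genes at an unadjusted p under 0.05; that variable set J11, J12 and J13 (0.444 to 0.5) apart from the rest (-0.325 to -0.084). It was also 0 without J11, J12 and J13. Total count alone stayed within 1.5 times (6213 and 615). Its scaling and that of TPM favour rising genes. Leaving out 1 library gave 2 to 11481. Other causes were not tested.

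The 2564 transcripts (2237 rising, 327 falling) became 12360 with DESeq2 (7221 and 5139), 4494 with limma-voom (2683 and 1811), 5663 with no filter, 1463 at 5 CPM in 5 libraries and 0 without J11, J12 and J13. Leaving out 1 library gave 11 to 6643. The 429 genes of isoform use became 163 by Simes p and 1 without J11, J12 and J13. The 940 on-off genes became 141 at 5 CPM. The coefficient of variation was 0.786 without size in the model and 0.581 without J11, J12 and J13. The relation of distance to size, positive over 10 libraries (permutation p 0.0106 to 0.023 there, with other distances, and without J1), turned to -0.338 without J11, J12 and J13. For detected genes, Spearman's permutation p over 10 libraries was 0.0477 (0.0716 adjusted over 3 relations) and above 0.05 under all 4 alternatives. Pearson's was above 0.05 in each. Over the 10 libraries less the 2 fish farthest from the median size, Pearson's r at 1 expected count was -0.049. It was 0.697 at 1 CPM, 0.565 at 0.1 CPM and 0.686 after thinning. J12 and J13 were equally far from the median, and only J12 was left out with J1. These r values pool J11 and J13 with the other fish. No slope of the 4 named genes turned sign where a fit tested it (none was tested at 5 CPM in 5 libraries, nor TRINITY_DN199115_c9_g6 without J11, J12 and J13); each lost its call with 2 size classes (adjusted p 0.144 to 0.209) and with the surrogate variable (adjusted p 0.0581 to 0.0617). There the slopes were 2.83 (3.55 before), -2.76 (-2.75) and -2.48 (-2.23) for TRINITY_DN200388_c2_g4, TRINITY_DN197246_c1_g4 and TRINITY_DN163868_c0_g1. TRINITY_DN200388_c2_g4 and both fallen genes also lost it without J2 (edgeR adjusted p 0.0505 to 0.0531). The fallen genes lost it without J12 or J13 as well (edgeR adjusted p 0.0629 to 0.0875). Depth limits the named genes that fell, at 5 to 67 counts. The gene lists could not be run.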

Other observations

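The tests in this part were chosen after the patterns they bear on were seen. For the sizes dealt at random among 7 fish, what would count for or against was written down before the outcome was known.

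A 203 bp transcript, TRINITY_DN237115_c7_g1_i1, singled out after its values were seen, took 20, 52.1, 42.1 and 21.0% of all TPM in J1, J2, J3 and J4. In the other libraries it took 0.297 to 1.07%. Its part of the expected counts was 0.461, 1.89, 1.36 and 0.474% in the same 4 fish. Its effective length was 16.45 to 21.04 bp there, and TPM divides by that length, so TPM of every other transcript was lowered in these fish. They are the 4 smallest, so the fit on log2 TPM, with 9628 genes rising and 1433 falling, was pushed towards rising genes. On log2 FPKM 8107 rose and 2215 fell. How much of the TPM split this transcript accounts for was not tested. TRINITY_DN117040_c3_g1 and 2 genes of another Trinity component moved together over the 10 libraries. The SD of their log2 ratio to it was at most 0.22, against an SD of 2.86 for its log2 level. The 3 genes held 3.36, 24.1, 32.8 and 9.09% of the counts in J1, J2, J3 and J4 and 0.235 to 0.472% in the others.

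Of the 100 most abundant genes, 24 lay under 1% of their level in J9 in each of J11, J12 and J13, and held 22.5 to 36.7% of the counts in J1 to J9 and 0.0161 to 0.0268% in J11, J12 and J13. Removal by a filter is argued against, because 0 of the 24 had a count of 0 in any of these 3 libraries. Reads drawn to a differing copy that was nearly absent from J1 to J9 are argued against too. In each pairing the 3 libraries held at most 3.3% of their counts in genes 100 times lower in the other library. That is far less than the 24 genes hold in J1 to J9. A copy less than 100 times lower there, or missing from the assembly, would not be seen, so such copies stay open. A lower share of 1 abundant tissue may explain the loss and cannot be told apart from other causes: the 24 genes had a mean correlation of 0.312 among J1 to J9, which 36.7% of random sets reached (median 0.274), but their joint share varied only 1.63 times there. A looser definition of 27 genes went the other way, with 0.171 against a random median of 0.345 and 98.3% of random sets as high, and their share varied only 1.41 times.

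The 16 genes found in J4, J6, J11, J12 and J13, with 0 counts in the other 5 libraries, lay in 14 Trinity components. Independent chance per gene is argued against, because the fullest of all other 5-library patterns held 3 genes. The make-up of J11, J12 and J13 is argued against as the whole cause, because the fullest other pattern of these 3 with 2 further libraries held 2 genes. The pattern was singled out for its count, so lower counts in the other patterns were partly set by that choice. J4 and J6 also lay together on the second principal component, at -156.3 and -152.7, against -9.7 to 151.5 in the others. Whether this bears on the pattern was not tested. Versions of the same sequences assembled as separate genes may account for some of the genes. For 8 of the 16, the summed level of their component was 1 CPM or more in all 10 libraries. That sum includes the gene itself, so its partners had to reach 1 CPM together only in the 5 libraries without the gene. The reciprocal pattern held 0 genes, so this explanation stays open. The fish were 2.2 to 3.3 cm long, the other 5 were 1.7 to 3.1 cm, and no biological explanation was tested.

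For the 5149 genes that followed size, of 100 orders of the sizes over all 10 fish, 1, the real one, gave as many, and the highest other gave 1809, with J11, J12 and J13 together at the large end (0.862 cm above the others on average) in both. This excludes chance only for 10 exchangeable libraries, and these 3 lie together. The place of J11, J12 and J13 among the largest fish may carry the count, which was 0 without them, although the fit then also had fewer fish and a narrower range of size. With their sizes kept and the other sizes dealt at random among the 7 remaining fish, 4 of 60 orders gave as many, the real one included, with a highest other count of 6825 and a median of 782, so a chance order of these 7 cannot be excluded at 0.05. A structure of the samples that sets J11, J12 and J13 apart is a candidate explanation for part of the calls, as a hypothesis found and tested on the same data. Growth itself stays open, as does anything else that followed the fish number.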
